A study of Rattus norvegicus with 2 samples.

How the data were processed

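Gene expression was measured in rat C6 glioma cells that stably express green fluorescent protein and were grown with 10% serum and 5 µg/ml puromycin. Per the labels' protocols, cells were stained with 5 µg/ml Hoechst dye for 90 minutes and sorted with lasers at 355 nm and 488 nm into dye-effluxing side population (SP) and dye-retaining main population (MP) cells. Cells of 3 sorting experiments were pooled for each population, and 0.2 µg of RNA was labelled with Cy3. There are thus 2 arrays and 1 array per group, and groups were taken from the sample titles.

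Per the file headers, the scanner files hold spot intensity values from Agilent Feature Extraction 9.5.3.1, a version the submitters' processing notes give too, run with a 1-colour protocol on the whole rat genome design. The processed intensity is background-subtracted and spatially detrended within an array, with low values replaced by surrogates, per the file headers. The authors deposited a value table as well, on a signal scale that no header or label states. Set against the scanner values, its entries equal the processed intensity divided by the array's 75th percentile, on a linear scale and rounded, with ratios of 0.999 (SD 0.287%) for 13363 probes of the SP array and 1.00 (SD 0.295%) for 13662 of the MP array with a processed signal above 200. Each column of that table has a median of 0.09 and is not centred per gene, and its direction is that of the scanner values. Neither array was saturated in any spot. Both arrays lie on 1 slide and were scanned once, so slide and scan do not separate the groups, and the position on the slide cannot be told apart from the group.

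Each array held 43379 non-control spots for 41012 probes. Spots with an outlier flag (88 on the SP array and 86 on the MP array) were left out, and spots of a probe were averaged on the log2 scale. Values are log2 of the processed signal minus the array's 75th percentile, and a linear level is given as a multiple of that percentile. A gene was measured where a probe was well above background on both arrays, and its brightest such probe gave its value. Differences are SP minus MP. The technical error combines the signal errors given by Feature Extraction for both arrays (median 0.20 on the log2 scale). Among probes spotted 10 times, the median SD of log2 signal within an array was 0.100 for SP and 0.0753 for MP. These errors describe the arrays, and the number of arrays limits the precision of every comparison. Where all probes of a gene were below background on 1 array, the difference is a bound, the bright value against the higher of the dim probe's own value and the lowest value well above background on that array.

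Gene names in the files are those of the array design. Suffixes for predicted or mapped genes were removed, and names were updated through a table of rat RefSeq genes (assembly GRCr8), used for names and for a check of chromosomes. Of the probes, 10826 matched by accession, 5210 by symbol and 3457 by a synonym, and 21519 kept the name in the files. A synonym was not used for 31 probes whose position lay on another chromosome than the gene of that synonym, as for mitochondrial COX2 and Ptgs2, a check added after values were seen. Probe positions are those of the files (rn4). Names that are accessions, clones or other placeholders (11610 of 22096 measured) stay in the counts and are not named.

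With 1 array per group, no test across samples was possible. Genes were counted by size, at least 2-fold (log2 of 1 or more). For each of 40 gene lists fixed before the data were examined, the median difference is given with its percentile among 10000 random lists of measured genes with a symbol, matched on mean signal in 20 bins, as a description of these 2 arrays. A 95% interval of a list median comes from 2000 resamples of its members, which are not independent, and describes how far the median rests on single members. A list stands apart when its median lies below the 2.5th or above the 97.5th percentile. The lists held 945 distinct genes, of which 867 have a probe of that name and 744 were measured on both arrays. The genes named in the text follow a rule fixed at the same time. They are the 15 highest and 15 lowest genes with a symbol whose brighter value exceeds the median of detected probes and whose difference exceeds 1.96 technical errors, and the 5 with the largest bound in each direction. Abcg2, Abcb1a, Abcb1b, Abcc1, Prom1, Nes, Sox2, Cd44, Gfap, S100b, Tf, Tfrc, Hmox1, Csf1 and Mki67 were always named. For each list up to 4 members with the largest differences beyond 2-fold were named, or 2 members where none reached it. Il6, Cxcl1, Nfkb2, Nfkbia, Fos, Nr4a1, Egr2, Arc, Pdgfrb, Axin2, Rundc3b, Abcb4, Crot, Dbf4 and list members with a bound of at least 2-fold were named after their values were seen, as were the genes of the closing observations.

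The calls were tested on simulated data for the comparison of SP and MP. Among 22096 simulated names with technical error alone, 25 of 50 with a true 2-fold change, 50 of 50 with a 3-fold change and 5 of 50 with a 1.5-fold change were called. Of 200 random lists of 20 genes, 8 stood apart (4.00%), and 46 of 50 lists shifted by 0.3 were above the 97.5th percentile.

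Alternatives were normexp background correction with an offset of 50 on mean and background signals, median, quantile, loess (fraction 0.3) and spike-in scaling (8 spike-in probes), no filter or a stricter filter on low signal, the mean of a gene's probes or its probe with the smallest error, and the authors' value table. Counts were also made at 1.5-fold and 4-fold and with a filter on the technical error. Lists were also scored by the mean, against unmatched random lists, and with bounds included. Random lists from all measured names, lists without shared members, and counts and lists without shifted genome windows were added after the data were seen, as were the windows under each setting. Genome windows of 10 megabases were compared with 100 shuffles. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, with R 4.3.3 and limma 3.58.1 for normexp.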

Results

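C6 is a rat glioma cell line. A subline that stably carries green fluorescent protein was stained with the DNA dye Hoechst and sorted by flow cytometry. Cells that pumped the dye out formed the side population (SP), which the labels call glioma stem cells, and cells that kept it formed the main population (MP). RNA taken directly after sorting was measured on 1-colour Agilent whole-genome arrays, with 1 array per population, each from a pool of 3 sorting experiments. The comparison asks how the transcripts of dye-effluxing cells differ from those of the remaining cells of the same culture. Both arrays shared 1 slide and 1 scan. Of 41012 probes, 65.4% were well above background on the SP array and 66.2% on the MP array, and no spot was saturated. The 75th percentile of signal was 436 on the SP array and 478 on the MP array. Because each group has 1 array, no difference below has a replicate check, and no p-value is given. The error beside a value is the scanner software's technical error of 1 pair of arrays, and it leaves out variation between cultures and sorts.

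SP and MP cells shared most of their transcript levels. Of 22096 names measured on both arrays, 1056 (4.78%) were at least 2-fold higher in SP and 735 (3.33%) were at least 2-fold lower. Among the 10486 names that are gene symbols, 516 were higher and 366 lower by that size. At least 4-fold differences were seen for 186 names higher and 141 names lower in SP. Log2 signals correlated at r = 0.98 across names, which are not independent replicates. In a simulation with the scanner software's technical error alone, 10 of 21896 unchanged names were called 2-fold. The size of that error sets this number, so it does not tell how many of the calls are technical. Of 169 called names with several measured probes, 159 had all probes on the same side and 97 had all probes at least 2-fold different.

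**Figure D1:**
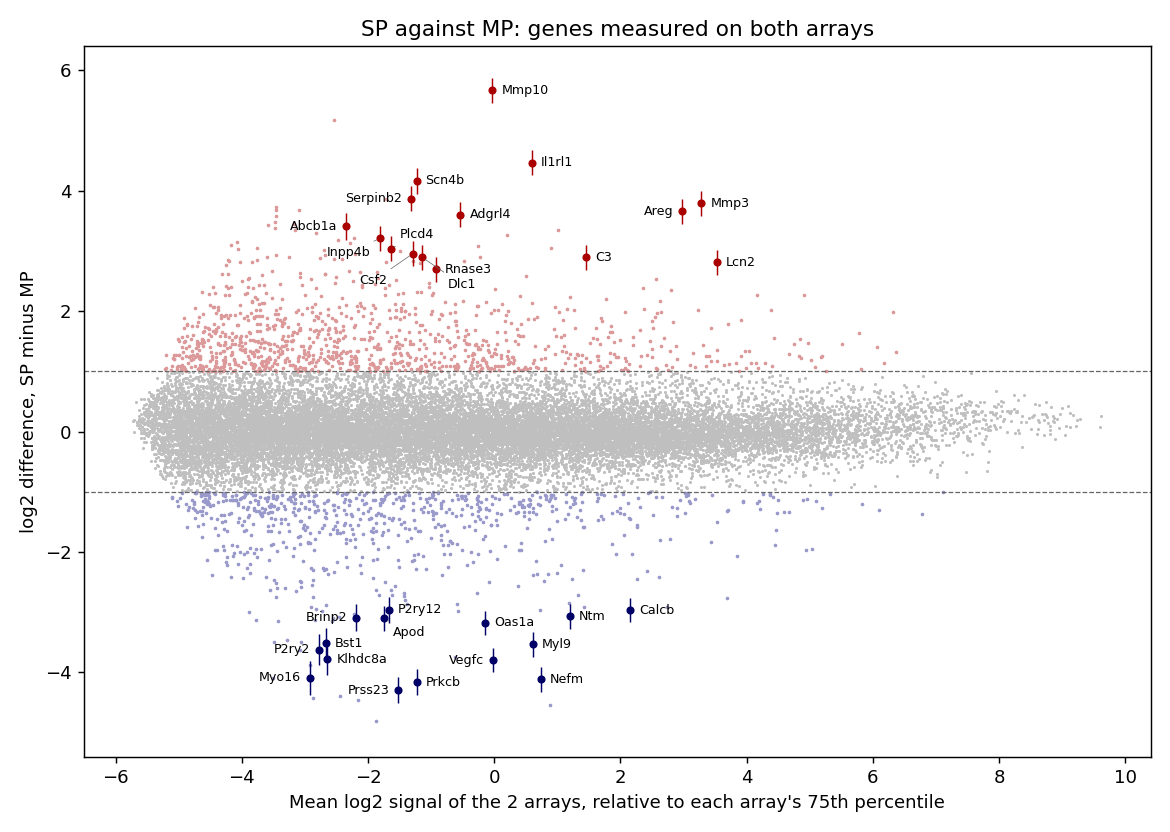
Log2 difference between SP and MP (vertical axis) against the mean log2 signal of both arrays relative to each array's 75th percentile (horizontal axis), 1 dot per name measured on both arrays. Red and blue mark names at least 2-fold higher or lower in SP (dashed lines), and labelled points with technical error bars are the 15 highest and 15 lowest genes, from Mmp10 at 5.67 to Prss23 at -4.30.

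The 15 highest genes in SP ranged from Mmp10 to Rnase3 and had varied known functions. Mmp10 and Mmp3, secreted metalloproteinases, were 50.8-fold (log2 5.67 ± 0.21) and 13.9-fold (3.79 ± 0.20) higher. Il1rl1, the receptor for the cytokine Il33, was 22.1-fold higher (4.47 ± 0.20), while Il33 itself was lower (-2.46 ± 0.25). Areg, a ligand of the epidermal growth factor receptor, was 12.6-fold higher (3.66 ± 0.20) and bright on the SP array, at 28.0 times that array's 75th percentile. Serpinb2, an inhibitor of plasminogen activators, was 14.6-fold higher, and the sodium channel subunit Scn4b was 18.0-fold higher. Csf2, which encodes a myeloid growth factor, the complement component C3 and the iron-siderophore binding protein Lcn2 were 7.74-fold, 7.42-fold and 7.01-fold higher. The adhesion receptor Adgrl4 (12.2-fold), the lipid phosphatase Inpp4b (9.25-fold), the phospholipase Plcd4 (8.20-fold), Dlc1 (7.44-fold) and Rnase3 (6.47-fold, named Ear11 in the files) completed the 15 highest with Abcb1a. The value of Dlc1 rests on 1 of its probes, since its other probe gave -0.21, and it was 2.54-fold higher with the mean of probes. All 15 were at least 2-fold higher with normexp background correction, whose offset shrinks dim genes, but 9 moved by over 1.5 times. Mmp10 was then 28.0-fold higher, Scn4b 8.11-fold, Adgrl4 7.40-fold, Serpinb2 7.21-fold, Dlc1 4.77-fold, Inpp4b 4.71-fold, Plcd4 4.52-fold, Csf2 4.28-fold and Abcb1a 4.01-fold.

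The 15 lowest genes in SP ranged from Prss23 to P2ry12 and also had varied known functions. Prss23, a serine protease, was 19.7-fold lower (log2 -4.30 ± 0.22), with both of its probes alike. Prkcb, a protein kinase C isoform, was 17.9-fold lower (-4.16 ± 0.21), the neurofilament gene Nefm 17.4-fold lower (-4.12 ± 0.20) and the unconventional myosin Myo16 17.1-fold lower. Vegfc, a lymphatic and vascular growth factor, was 13.9-fold lower, and Myl9, a myosin light chain of contractile cells, was 11.6-fold lower. The interferon-induced Oas1a was 9.05-fold lower. Klhdc8a, the nucleotide receptors P2ry2 and P2ry12, Bst1, the lipid carrier Apod, Brinp2, the neural adhesion gene Ntm and the calcitonin gene relative Calcb were between 7.80-fold and 13.8-fold lower. With normexp all 15 were at least 2-fold lower, but 9 moved by over 1.5 times. Prkcb was then 7.85-fold lower, Prss23 7.66-fold, Apod 4.23-fold, Myo16 4.13-fold, Klhdc8a 3.96-fold, P2ry12 3.86-fold, Brinp2 3.68-fold, P2ry2 3.63-fold and Bst1 3.53-fold.

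Some genes were well above background on 1 array only, so their differences are bounds. There were 750 such names on the SP array and 1029 on the MP array, and the bound reached 2-fold for 288 and 193 of them. Scg3, a secretory granule protein, was at least 46.0-fold higher in SP. Cd74, the invariant chain of antigen presentation, was at least 21.1-fold higher, Eaf2 at least 17.0-fold, Ppfia4 at least 15.9-fold and Mas1 at least 15.2-fold. In the other direction, Tnfrsf17 was at least 23.0-fold lower in SP, Snca, which encodes alpha-synuclein, at least 22.0-fold, Wnt6 at least 17.2-fold, Pla2r1 at least 14.8-fold and Or7g22 (named Olr1129 in the files) at least 12.8-fold. Beside Cd74, members of the gene lists with a bound of at least 2-fold were Ptgs2, the inducible cyclooxygenase (at least 7.68-fold higher), Sfrp2 (4.49-fold), Enpp6 (3.64-fold), Ereg (3.06-fold), Hgf (2.97-fold), Csf3 (2.86-fold), Slc4a1 (2.49-fold) and Slc17a7 (2.08-fold) in SP. In MP they were the growth factor gene Nrg1 (at least 8.20-fold higher), Lmo2 (2.81-fold), Tek (2.77-fold), Esam (2.19-fold) and Rrm2b (2.13-fold).

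Among ABC efflux transporters, the pair of genes for P-glycoprotein stood out and the rest did not. Abcb1a was 10.7-fold higher in SP (log2 3.41 ± 0.22) and Abcb1b 5.25-fold higher (2.39 ± 0.21). With normexp background correction the differences were 2.00 and 1.59. Their probes lie at 21795859 to 21795918 and 21899463 to 21899522 of chromosome 4 (rn4). Cross-hybridisation between these related genes was not checked by sequence and cannot be excluded. The 16 other names within 1 megabase of Abcb1a, Abcb1b included, had a median of 0.24, and Rundc3b among them was 4.94-fold higher. The other 14 measured transporters were under 2-fold, Abcc1 among them at 0.12 ± 0.20, and the list median of 16 members was 0.11 (percentile 85.1). Abcg2, the transporter often linked to the side population, was well above background on the MP array but not on the SP array. Its linear level, as a multiple of each array's scaling percentile, was 0.0208 on the SP array and 0.0206 on the MP array. These low values show no difference between SP and MP, and no fold is given for Abcg2, because its bound is under 1.

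Stem cell marker genes were, as a list, slightly lower in SP. The median of 18 neural and glioma stem cell markers was -0.28 (percentile 0.27; 95% interval from resampled members -0.58 to 0.38), with 7 higher and 11 lower and 2 at least 2-fold lower, the surface glycoproteins Podxl (-1.47 ± 0.20) and L1cam (-1.32 ± 0.21). Sox2, a neural progenitor transcription factor, was at -0.52 ± 0.20, the intermediate filament gene Nes at -0.31 ± 0.20 and the hyaluronan receptor Cd44 at 0.12 ± 0.20, with its other probe at 0.67. Prom1 was not well above background on either array. This list kept its direction but lay inside the central 95% of random lists without the low-signal filter (percentile 12.5) and when scored by its mean. Of 6 pluripotency factors, 4 were higher, with a median of 0.44 (percentile 98.9; interval -0.92 to 0.98), and the growth regulator Myc was the 1 member at least 2-fold higher (1.33 ± 0.20). The mean of these 6 was 0.17 (percentile 78.7).

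Inflammatory signalling genes formed the list with the highest median. The median of 14 measured NF-kB targets was 0.95 (percentile 100 of 10000 random lists of like signal), with 13 higher in SP and 6 at least 2-fold higher, and the interval from resampled members was 0.65 to 1.86. These included C3, Lcn2, the monocyte chemokine Ccl2 (3.98-fold, log2 1.99 ± 0.20) and the surface protein Cd83 (1.86 ± 0.23). Of 20 chemokines and cytokines, 17 were higher, 7 at least 2-fold, and the median was 0.52 (percentile 100; interval 0.22 to 1.52). Csf2, the alarmin Il1a (2.67 ± 0.27) and the chemokine Ccl7 (2.27 ± 0.20) led this list, Csf1 was at 0.27 ± 0.20, and Il33 was the 1 member at least 2-fold lower. The lists share Ccl2, Cxcl1 and Il6. Without shared members their medians were 0.94 and 0.32 (percentile 99.4). With Csf3 and other chemokines measured on 1 array at their bound, the chemokine median was 0.70. The probes of Nfkbia, the NF-kB inhibitor, disagreed (-0.40 and 0.84). Among markers of macrophages, which express many of these genes, Cd74 and Lyz2 were higher in SP, while the median of that list was -0.11. Nfkb2, a member of the first list, lies in a chromosome 1 segment described below where most genes were higher in SP.

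Immediate early genes, which respond within minutes to growth factors and stress, went both ways. Of 23, 14 were higher and 8 at least 2-fold higher, and the median was 0.38 (percentile 100; interval -0.09 to 1.09). The transcription factor genes Nr4a3 (2.37 ± 0.20), Fosl1 (2.35 ± 0.20) and Fosl2 (1.53 ± 0.21) and the phosphatase gene Dusp5 (2.27 ± 0.20) had the largest values. The other 9 members were lower, none of them 2-fold, among them Nr4a1 (-0.90 ± 0.20), Egr2 (-0.73 ± 0.20), Arc (-0.71 ± 0.20) and Fos (-0.27 ± 0.20). The 3 probes of Nr4a3 ranged from -0.65 to 2.46, and Dusp5 lies in the same chromosome 1 segment. Beside these 3 lists, RNAs known to be short-lived were also higher in SP. Of 43 such RNAs outside the 3 lists, 34 were higher and 16 at least 2-fold higher, with a median of 0.73 (percentile 100).

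Proliferation genes were modestly higher in SP as a group. Of 26 genes of G1/S and DNA replication, 24 were higher, with a median of 0.45 (percentile 100; interval 0.35 to 0.60), but 1, the origin recognition gene Orc1, passed 2-fold (1.36 ± 0.20). Of 31 genes of G2/M and mitosis, 27 were higher, with a median of 0.32 (percentile 100; interval 0.20 to 0.46), and the mitotic genes Kif11 (2.05 ± 0.21), Aurka (1.68 ± 0.20) and Cks2 (1.02 ± 0.20) passed 2-fold. Kif11 lies in the chromosome 1 segment. The median of 6 histone genes was 0.17 (percentile 82.4), led by H2ax (0.80 ± 0.20) and H2az1 (0.41 ± 0.20). Mki67 has no probe of that name here. Of 17 cyclin-dependent kinase inhibitors and quiescence genes, 10 were higher (median 0.21, percentile 98.8, interval -0.16 to 0.63). Cdkn1c was 2.84-fold higher, although its other probe gave -0.20. That list lay inside the central 95% of random lists in 5 alternatives, with percentiles of 83.1 to 97.0.

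The p53, heat shock, ribosomal protein, hypoxia and TGF-beta lists were higher in SP. Of 18 genes of the p53 and DNA damage response, 12 were higher (median 0.40, percentile 100, interval -0.21 to 0.65), led by the polo-like kinase Plk2 (1.65 ± 0.20), Tp53inp1 (1.11 ± 0.20) and Mdm2 (1.05 ± 0.20). Of 18 heat shock and chaperone genes, 15 were higher (median 0.38, percentile 100, interval 0.10 to 0.50), with Hspa1a 2.10-fold higher and the small chaperone Cryab 2.48-fold lower. Of 48 cytosolic ribosomal protein genes, 43 were higher by small amounts (median 0.30, percentile 100, interval 0.20 to 0.37) and none passed 2-fold, with Rplp0 at 0.80 ± 0.20 and Rpl4 at 0.70 ± 0.20. Their median was 0.12 with quantile normalization and 0.15 with loess, and such probes may also bind pseudogene transcripts. Of 26 hypoxia response genes, 16 were higher (median 0.22, percentile 99.7, interval -0.08 to 0.47). The transcription factor gene Bhlhe40 was higher (1.24 ± 0.20), and Epas1 (-1.96 ± 0.26) and Egln3 (-1.56 ± 0.21), both of oxygen sensing, were lower. The median of 18 TGF-beta and BMP targets was 0.19 (percentile 97.7, interval -0.03 to 0.45), with 13 higher, although the member beyond 2-fold, the feedback inhibitor Pmepa1, was lower (-1.30 ± 0.20). The p53, hypoxia and TGF-beta lists lay inside the central 95% of random lists without the low-signal filter, and the last 2 also when scored by the mean.

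Oligodendrocyte lineage genes were lower in SP. Of 11 measured markers, 10 were lower and 5 at least 2-fold lower, with a median of -0.88 (percentile 0, interval -1.37 to -0.11). The myelin proteolipid gene Plp1 was 7.56-fold lower (-2.92 ± 0.20, both probes alike), the lineage transcription factors Olig1 and Sox10 were at -1.87 ± 0.20 and -1.34 ± 0.20, and the progenitor proteoglycan Cspg4 was at -1.37 ± 0.20. With 3 members measured on 1 array set at their bound, among them Enpp6 at least 3.64-fold higher in SP, the median was -0.29 (percentile 1.00). Of 13 astrocyte markers, 8 were lower (median -0.19, percentile 7.15), but the median was 0.076 without the low-signal filter. The glial filament gene Gfap (-1.45 ± 0.21) and the growth factor receptor Fgfr3 (-1.77 ± 0.20) were lower and the glutamate transporter Slc1a3 was higher (1.15 ± 0.20). S100b was not well above background on either array. The median of 11 neuronal markers was -0.21 (percentile 7.07), with Elavl3 higher (1.06 ± 0.29) against Nefm, and it was 0.19 without that filter.

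The interferon response, unfolded protein response and matrix lists were lower in SP. Of 25 interferon response genes, 20 were lower (median -0.32, percentile 0.03, interval -0.50 to -0.16), with the lowest values for Oas1a, the antiviral GTPase Mx2 (-2.07 ± 0.33) and the transcription factor Irf7 (-1.65 ± 0.20). Of 27 unfolded protein response and ATF4 targets, 19 were lower (median -0.21, percentile 0.52, interval -0.42 to -0.03), yet Chac1 (1.10 ± 0.20) and Dnajb9 (1.08 ± 0.20) were higher and Stc2 was lower (-1.04 ± 0.20). Scored by its mean, this list lay inside the central 95% of random lists. Of 37 extracellular matrix and adhesion genes, 23 were lower (median -0.17, percentile 0.92, interval -0.41 to 0.02). Periostin, encoded by Postn (-3.50 ± 0.32), and the basement membrane genes Col4a2 (-1.74 ± 0.20) and Lama4 (-1.50 ± 0.20) were lower, opposite to Mmp3. With normexp this list lay inside the central 95% of random lists. Mesenchymal and pericyte markers had a median of -0.12 (percentile 16.6) but a mean of -0.84, since 5 of 14 were at least 2-fold lower. These were Myl9, Postn, the collagen genes Col3a1 (-2.03 ± 0.20) and Col1a1 (-2.71 ± 0.20), and Pdgfrb. The 3 probes of Col1a1 ranged from -2.71 to -0.61.

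Iron handling and growth factor genes went both ways. Of 20 iron genes the median was 0.12 (percentile 90.9), with 4 at least 2-fold higher and 2 at least 2-fold lower. Beside Lcn2, the heme oxygenase gene Hmox1 (2.77-fold, 1.47 ± 0.20), the heme carrier Hpx (1.48 ± 0.24) and the transferrin receptor Tfrc (1.09 ± 0.20, 3 probes alike) were higher, and transferrin itself, Tf, was 2.54-fold lower (-1.34 ± 0.20). Of 31 growth and angiogenic factors, 4 were at least 2-fold higher and 6 at least 2-fold lower, with Areg on one side and Vegfc, Angpt1 (-2.08 ± 0.21) and Angpt2 (-1.97 ± 0.33) on the other. Their median was 0.04 (percentile 78.0) and their mean -0.14, and the median turned negative with median scaling, quantile normalization and loess. Markers of other cell types did not stand apart. The median was -0.11 (percentile 20.6) for 9 macrophage and microglia markers, whose member Lyz2 was higher (1.67 ± 0.29) and whose mean was 0.02. Without the low-signal filter this median was 0.12. The median was -0.14 (percentile 20.9) for 5 endothelial markers, with Flt1 at 1.05 ± 0.21 and Vwf at -1.39 ± 0.24, and this sign turned with normexp and without the filter (0.16). It was 0.23 (percentile 83.3) for 6 erythroid and hematopoietic progenitor markers, with Ahsp at 1.34 ± 0.21.

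The remaining lists lay inside the central 95% of random lists. Signalling lists had medians of 0.03 (percentile 47.5) for 17 Notch genes, -0.09 (percentile 20.8) for 20 Wnt genes and -0.08 (percentile 28.6) for 7 Hedgehog genes. The Notch ligands Dll1 (1.17 ± 0.21) and Dll3 (1.01 ± 0.21) were higher, and Dkk3 (-1.57 ± 0.21), Fzd2 (-1.18 ± 0.20), Lef1 (-1.07 ± 0.20) and Gli2 (-1.08 ± 0.21) were lower, while the Wnt targets Myc and Axin2 (1.00 ± 0.22) were higher. Metabolic lists had medians of 0.04 (percentile 68.9) for glycolysis, with Slc2a1 at 0.67 ± 0.20 and Aldoc at -0.65 ± 0.20, and -0.11 (percentile 3.05) for the mitochondrial respiratory chain, with Ndufb8 at 0.60 ± 0.20 in the chromosome 1 segment and Ndufs8 at -0.60 ± 0.20. Cholesterol genes had a median of -0.05 (percentile 40.4) with Hmgcr at 0.99 ± 0.20 and Tm7sf2 at -0.93 ± 0.20, and a mean of 0.00379. Fatty acid genes had a median of -0.07 (percentile 28.2) with Fabp5 lower (-1.01 ± 0.20). NRF2 and glutathione genes had a median of 0.11 (percentile 91.7), with Hmox1 as the member beyond 2-fold. Apoptosis regulators had a median of 0.02 (percentile 69.1), with Casp7 higher (1.25 ± 0.20, chromosome 1 segment) and Bik lower (-1.84 ± 0.23). Antigen presentation genes had a median of -0.21 (percentile 4.72), with Psmb9 at -0.51 ± 0.20 and RT1-A2 at -0.33 ± 0.20. The spliceosome list had a median of 0.03 (percentile 77.3), with Srsf2 at 0.74 ± 0.20 and Srsf5 at 0.50 ± 0.20. The proteasome list had -0.04 (percentile 28.6), with Psmc3 at -0.36 ± 0.20 and Psmb3 at -0.33 ± 0.20. The lysosome list had -0.09 (percentile 18.3), with Gpnmb at -0.57 ± 0.20 and Glb1 at -0.52 ± 0.20. Signs of the glycolysis, NRF2, Notch, apoptosis and spliceosome medians turned under at least 1 other scaling, that of the Hedgehog median turned with normexp and without the low-signal filter, and that of the Wnt median turned with the mean of probes and with the probe of smallest error. With members measured on 1 array at their bound, medians were -0.23 for stem cell markers, 0.38 for the p53 response, 0.18 for hypoxia, 0.17 for TGF-beta targets, -0.25 for astrocyte, -0.09 for neuronal, -0.08 for macrophage, -0.49 for endothelial and 0.14 for erythroid markers. They were 0.09 for ABC transporters, 0.07 for iron handling, 0.08 for growth factors, 0.04 for Notch, -0.20 for antigen presentation and 0.10 for Hedgehog genes. In all, 17 of 40 lists stood apart, 12 higher and 5 lower, where 2 would be expected for lists of unrelated genes. The members of a list are not independent and some lists share members. The 2 therefore does not tell how many lists would stand apart between 2 arrays of 1 population. The interval from resampled members spanned 0 for 8 of these 17 lists, the stem cell, pluripotency, quiescence, p53, immediate early, hypoxia, TGF-beta and matrix lists, and lay on the side of the median for the other 9.

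The calls of some list members depended on the background correction. Of 94 named genes at least 2-fold different, 21 were under 2-fold with normexp. Those higher in SP were then at 0.96 for Cks2, 0.94 for Tp53inp1, 0.85 for Cd83, 0.82 for Ahsp, 0.72 for Dll3 and Flt1, 0.67 for Dll1, 0.59 for Hpx, 0.49 for Lyz2 and 0.37 for Elavl3. Those lower were at -0.95 for Lef1, -0.93 for Stc2, -0.91 for Il33, -0.85 for Dkk3 and Bik, -0.78 for L1cam, -0.72 for Gli2, -0.62 for Epas1, -0.61 for Mx2, -0.54 for Vwf and -0.51 for Angpt2. The values of Kif11 (1.44), Il1a (1.03), Postn (-1.34) and Angpt1 (-1.23) moved by over 1.5 times in fold and stayed beyond 2-fold. With the mean of probes, Nr4a3 was at 1.39, Col1a1 at -1.42, and Cdkn1c (0.65), Flt1 (0.82) and Chac1 (0.96) were under 2-fold, and Mdm2 was at 1.86 with its probe of smallest error. Among the genes named by the fixed rule, Cks2, Dll3, Flt1 and Mdm2 fell just under 2-fold with median scaling, Dll3 and Elavl3 with quantile normalization and Dll3 with loess.

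**Figure D2:**
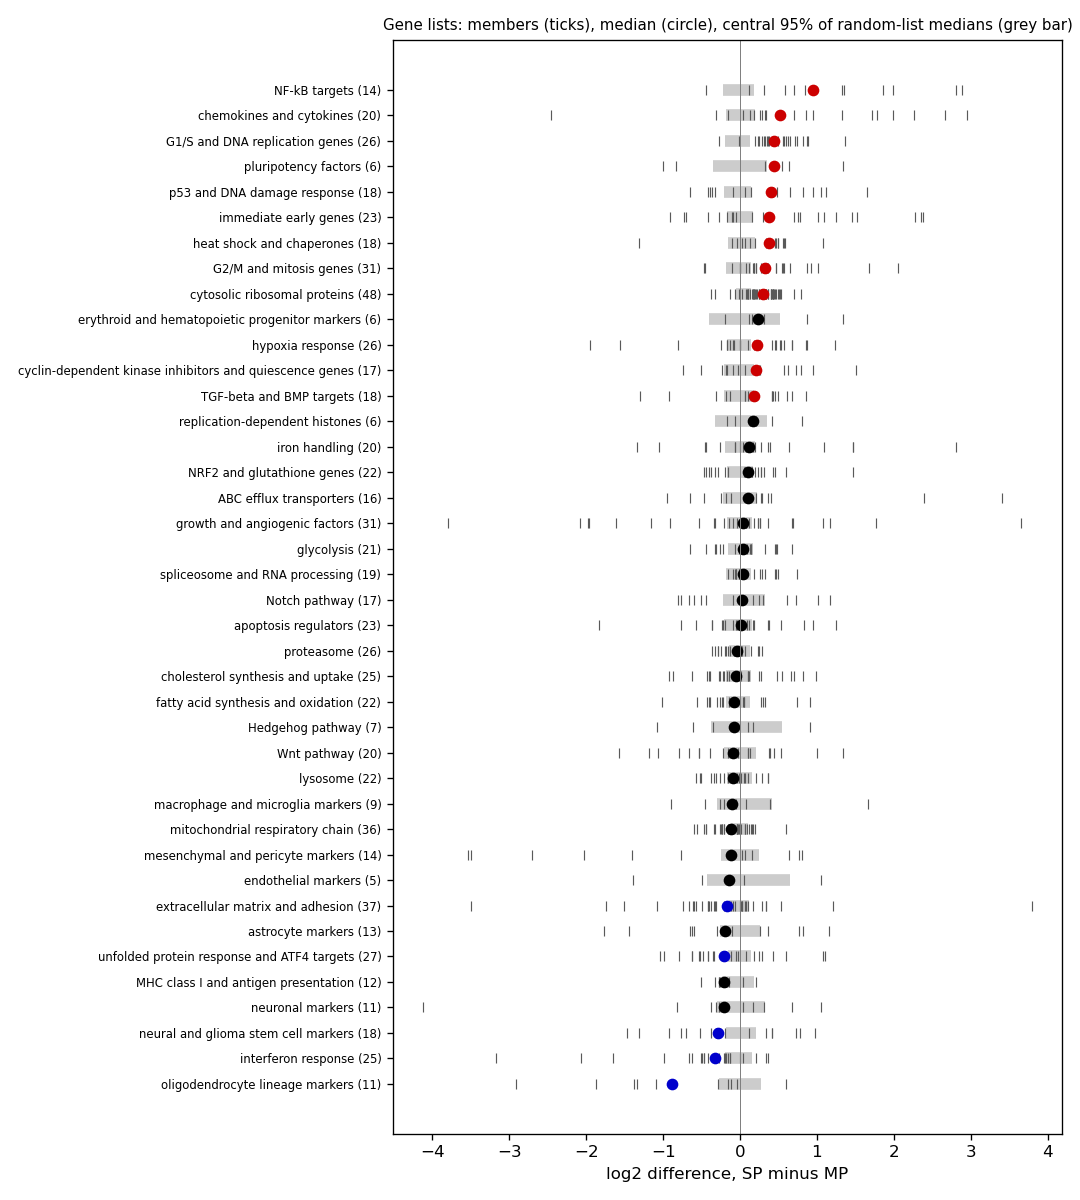
Log2 difference between SP and MP (horizontal axis) for the members of each list (ticks; number measured in parentheses), with the list median (circle; red or blue where it lies outside the central 95% of random lists, grey bar). NF-kB targets lie at the top with a median of 0.95 and oligodendrocyte lineage markers at the bottom with -0.88.

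Differences were not spread evenly along the genome. Of 266 windows of 10 megabases with at least 15 measured names, 9 had a median more than 0.25 from that of all names, against at most 2 in 100 shuffles of the values over positions. Neighbouring windows of chromosome 1 (rn4) from 240000001 to 270000000 made up 3 of the 9, with medians of 0.48, 0.86 and 0.50. In this segment, 122 of 134 genes with a symbol were higher in SP, and 55 of its 262 names were at least 2-fold higher. Serpinb2, Bik and Dnajb9 lie in other shifted windows, on chromosomes 13, 7 and 6, and the median of genes with a symbol in the window of Serpinb2 was 0.0054. Leaving out all names in the 9 windows left 982 names at least 2-fold higher and 708 lower.

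**Figure D3:**
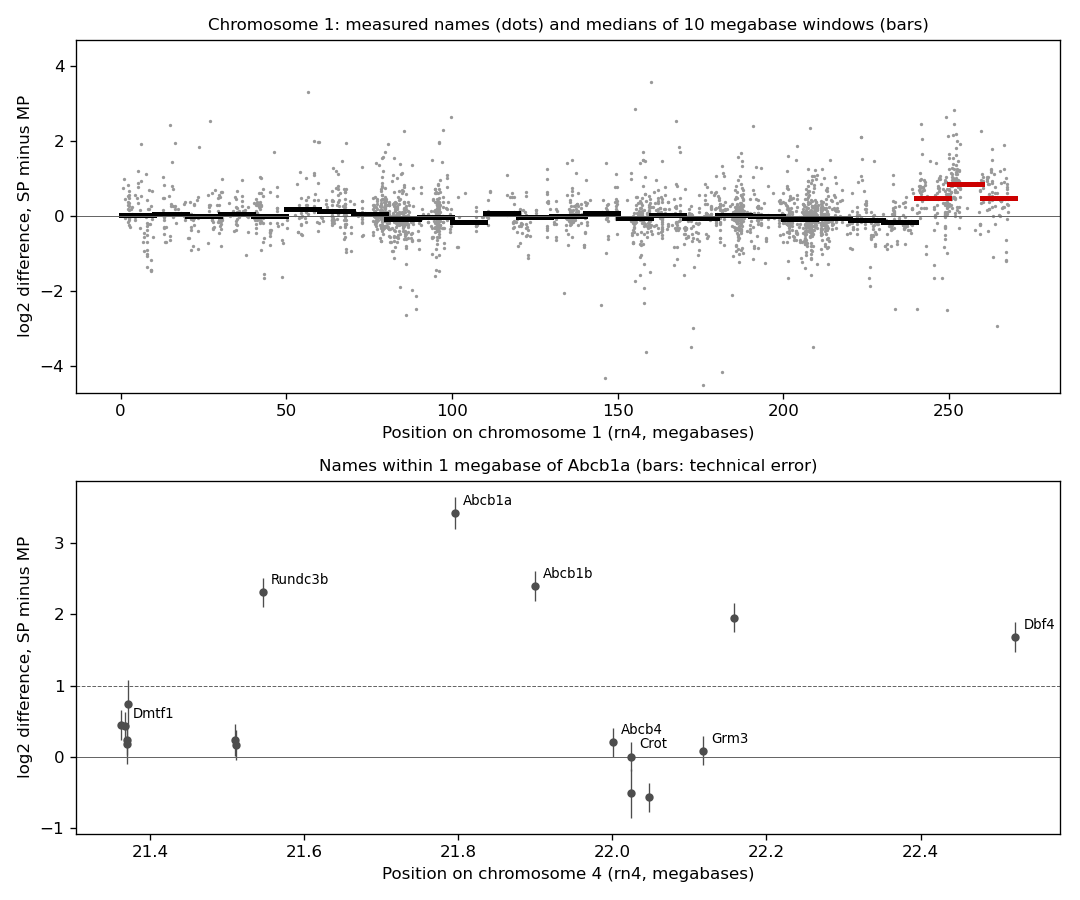
Log2 difference between SP and MP by probe position on chromosome 1 (top, 1 dot per name, bars for medians of 10 megabase windows, red where shifted by more than 0.25) and within 1 megabase of Abcb1a on chromosome 4 (bottom, with technical error bars). The last 3 windows of chromosome 1 have medians of 0.48, 0.86 and 0.50, and Abcb1a, Abcb1b, Rundc3b, Dbf4 and a transcript without a symbol lie above the dashed 2-fold line while Abcb4 and Crot lie near 0.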

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

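No paired analysis was possible because each population has 1 array. With 1 array per group no alternative can show how the values would vary between cultures, and signal over background limits the dim genes. Among the alternatives given here, the tests chosen only after the result was seen are random lists from all names, lists without shared members, counts and lists without shifted windows, and window counts under each setting. The list directions that stood apart held in every alternative, none of the 1150 values of named genes under alternatives turned a 2-fold call around, and 1083 moved by less than the technical error. Of the 67 that moved more, 57 did so with normexp, whose offset shrinks dim genes. No scaling moved the median of all names by more than 0.1 or the share of higher calls by more than 10 points.

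Counts depended on the filter, the background correction and the fold chosen. Normexp gave 420 names at least 2-fold higher and 335 lower, of which 419 and 335 were among the main calls. Without the low-signal filter there were 2529 higher and 1813 lower, and with the stricter filter 574 and 424, from more or fewer genes tested. At 1.5-fold there were 2544 and 1947, and at 4-fold 186 and 141. Names on 1 array with a bound of at least 4-fold numbered 156, and with normexp 57 had a bound of at least 2-fold. The added count of shifted genome windows was 3 with normexp, all in the chromosome 1 segment, and 4 without the filter.

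Of the 17 lists that stood apart, 9 did so in every alternative that was not added. Without the low-signal filter, medians lay inside the central 95% of random lists for stem cell markers (-0.038), pluripotency factors (0.26), the p53 response (0.16), hypoxia (0.14), quiescence genes (0.14) and TGF-beta targets (0.17), and the antigen presentation list moved outside it (-0.18). Taken as means, the stem cell markers (-0.19), pluripotency factors (0.17), quiescence genes (0.24), unfolded protein response (-0.15), hypoxia (0.11) and TGF-beta targets (0.12) lay inside, the mesenchymal list moved outside (-0.84) and the interferon list was at -0.50. With normexp, the quiescence genes (0.12) and the matrix list (-0.11) lay inside, and iron handling (0.15) and the respiratory chain (-0.15) moved outside. The stricter filter left quiescence genes at 0.065 and put the mesenchymal list outside at -0.44. With the mean of probes, TGF-beta targets were at 0.14, inside, and astrocyte markers at -0.29, outside. Against unmatched random lists, quiescence genes (0.21) and TGF-beta targets (0.19) lay inside. With bounds included, TGF-beta targets (0.17) lay inside and endothelial markers (-0.49) moved outside. Ribosomal protein genes kept their place with smaller medians under quantile normalization (0.12) and loess (0.15), and the spliceosome median was -0.022 with median scaling. In the added alternatives, random lists from all names put TGF-beta targets (0.19) inside and the respiratory chain (-0.11) and antigen presentation (-0.21) outside, and leaving out shifted windows put the respiratory chain outside (-0.13). The causes of these list changes were not tested, beyond the members that filters and bounds added or removed.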

Other observations

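The tests of a signal-dependent difference, of macrophage RNA and of the chromosome 1 segment were chosen only after the results were seen, the test with symbol genes alone was added once the shifted windows were known, and the genes of the next paragraph were chosen by their values.

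Beside Mmp10 and Mmp3, other metalloproteinase genes near them on chromosome 8 were higher in SP. Mmp13 was 8.32-fold higher (log2 3.06 ± 0.29) and Mmp12 at least 10.5-fold higher. Family members on other chromosomes went both ways, with Mmp9 2.32-fold higher and Mmp15 (-1.56 ± 0.21) and Mmp24 (-1.07 ± 0.23) lower. In the plasminogen system, the urokinase receptor gene Plaur was 3.29-fold higher (1.72 ± 0.20), while Plat (-0.17 ± 0.21) and Serpine1 (0.10 ± 0.20) differed by less than the technical error. Of genes for ligands of the epidermal growth factor receptor, Areg was 12.6-fold higher, Ereg at least 3.06-fold, Hbegf 1.61-fold and Tgfa 1.59-fold, while Egf was at 0.23 ± 0.21. In the interleukin-1 family, Il1a, the receptor antagonist Il1rn (2.83-fold) and Il1rl1 were higher, while the shared receptor chain Il1rap (1.74-fold) and Il33 were lower. Ptgs2, which encodes the inducible cyclooxygenase, was at least 7.68-fold higher.

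The higher NF-kB target and chemokine lists remained after loess removed any trend with signal, with medians of 0.96 and 0.50, both at percentile 100. Random lists were already matched on mean signal, so this shows that the sizes of the medians held and is no separate check of the percentiles. Against macrophage RNA in the SP pool of this cell line, the 9 measured of 14 abundant macrophage transcripts had a median of -0.11 (95% interval from resampled members -0.46 to 0.38). This is under 0.47, which is 0.5 of the NF-kB median. Aif1, Itgam and C1qa were not well above background on either array, and Ptprc and Fcer1g have no probe of that name. Cd74 is not among the 14, and the fixed macrophage list with Cd74 at its bound had a median of -0.08. Lyz2 and Cd74, which such cells express, were higher in SP all the same, but C1qb was lower (-0.90 ± 0.20). A loss of short-lived RNA in the MP cells stays open, since short-lived RNAs outside the inflammatory and immediate early lists had a median of 0.73, outside the -0.15 to 0.08 of random lists, with Tiparp (1.99 ± 0.20) and Rnd3 (1.90 ± 0.20) highest and Socs2 lowest (-1.17 ± 0.30). Of these 43, 13 are in other fixed lists and many respond to growth factors or stress, so a signalling difference between SP and MP may give the same values. MP cells were sorted for keeping the Hoechst dye, so an effect of the dye cannot be told apart from the population. The immediate early genes, which that set leaves out, went both ways, with 14 of 23 higher in SP and 9 lower. Nr4a1 (-0.90 ± 0.20) and Fos (-0.27 ± 0.20) were among the lower ones, so a loss of short-lived RNA in MP would not account for all of them.

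For the lower oligodendrocyte lineage list, the technical explanations that were tested found no value in their favour. After loess its median was -0.88 (percentile 0), which adds little, because the random lists were already matched on mean signal. The 302 detected spots within 3 rows and columns of its spots had a median difference of -0.0096, so a regional artefact would have had to spare the neighbours. A lower share or level of oligodendrocyte-like transcripts in SP cells is a hypothesis that rests on 11 genes of 2 arrays, and its size depends on 3 members measured on 1 array.

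Place in the genome was weighed as the third pattern, with the hypothesis that SP and MP cells may differ in DNA copy number. The test found 9 shifted windows, against a highest value of 2 in 100 shuffles. Several names for 1 transcript could inflate such windows. With genes that have a symbol alone, 15 of 249 windows of at least 10 genes were shifted, against at most 8 in 100 shuffles. This does not show that each of the 9 windows holds. Symbol genes of the chromosome 1 windows had medians of 0.62, 0.86 and 0.67. Those of the shifted windows on chromosomes 4 and 13 had medians of -0.057 and 0.0054. Against a few strongly differing genes as the whole source of the chromosome 1 segment, 90.8% of its 98 genes under 2-fold were higher in SP, while the 3 neighbouring windows with the highest median in each of 100 shuffles reached at most 76.2%. The median of its 134 genes was 0.71, and it stayed between 0.56 and 0.75 above the genome median in all alternatives of the gene values. It was lowest without the low-signal filter, where 2 of the 3 windows were shifted. A gain of this segment in many SP cells, or its loss in MP cells, is thus a candidate that sequencing of DNA from both populations could settle.

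Whole chromosomes showed smaller shifts, which were looked at after the windows. Genes on chromosome 12 had a median of 0.20, with 72.8% of 320 higher in SP, and genes on chromosome 7 had -0.17, with 33.1% of 674 higher, whereas the largest chromosome shift in 100 shuffles was 0.10. Without the low-signal filter, the shift from the genome median was 0.11 for chromosome 12, against 0.21 with it, and -0.14 for chromosome 7, against -0.16.

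A gain of the Abcb1 region was tested as a source of the Abcb1a difference and cannot be told apart from regulation of its genes. The 16 other names within 1 megabase had a median of 0.24, but the interval from resampled names reached from 0.17 to 0.96. Rundc3b, on the near side of Abcb1a, was 4.94-fold higher (2.31 ± 0.20), and Dbf4, farther along, 3.20-fold higher (1.68 ± 0.20). Abcb4 (0.21 ± 0.20), Crot (0.0046 ± 0.20) and Grm3 (0.09 ± 0.20), which lie between Abcb1b and Dbf4, were close to 0. A transcript without a symbol between Grm3 and Dbf4 was higher (1.95 ± 0.20). Of the 16 names, 14 were higher in SP and 4 at least 2-fold higher, but names close to 0 lay between the strongly higher ones.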
